A study of Homo sapiens with 4 samples.

How the data were processed

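Total RNA from XTC.UC1 cells, an oncocytic (mitochondria-rich) thyroid carcinoma cell line, was profiled on 1-colour Agilent human miRNA arrays with Cy3 labelling. Per the labels, 2 cultures received a scramble siRNA and 2 received an siRNA against PRC, the PGC-1-related coactivator encoded by PPRC1, at 30 nM for 48 h, and each group holds biological replicates 1 and 2. The arrays measure miRNAs, so PRC mRNA itself was not measured and the knockdown was not checked here.

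The deposited scanner files hold spot intensities made with Agilent Feature Extraction 10.1.1.1, per the file headers. The processed signal is, per the file headers, a background-subtracted intensity with spatial detrending, and it was not normalized between arrays. The same files hold the raw spot mean and local background intensities, the software's total intensity per miRNA, and flags for outlier, saturated and well-above-background spots. All 4 arrays came from 1 scan, so slide or scan could not be fitted as a block. The authors also deposited a table of processed values for 596 probes whose making is not given in the sources used here. Its scale, centring and direction stay unknown, because no column followed the scanner signals of the probes it names, so its rows were not named and it entered no comparison.

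Each array carried 12784 non-control spots for 2421 probes, which addressed 723 human and 76 viral miRNAs. Control spots and spots marked as outliers were left out, the processed signals of the remaining spots were averaged per probe, and the probes of a miRNA were summed. Of 35 miRNAs with at least 2 probes measured on the 3 arrays other than scramble replicate 2, the probes differed in sign for 3 (PRC siRNA replicate 1 against scramble replicate 1) and 1 (PRC siRNA replicate 2). A probe counted as well above background when at least 50% of its spots carried that flag, and a miRNA when any of its probes did. Before the data were examined, each array was to be divided by its 75th percentile over the human miRNAs well above background on all 4 arrays. No miRNA met that condition, so the percentile was taken over the 66 miRNAs well above background on the 3 arrays other than scramble replicate 2, a change made after seeing the data. The percentiles were 822, 409, 202 and 2827 for scramble replicates 1 and 2 and PRC siRNA replicates 1 and 2. Scaled signals were floored at 0.01 of the percentile and taken to log2, so 0 stands for the percentile of that array. Values at the floor have no order.

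Human miRNAs well above background on both arrays of at least 1 group were tested with limma 3.58.1 (lmFit and eBayes, group alone in the model, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 66 tested miRNAs entered through the PRC siRNA arrays. The 24 miRNA lists were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. camera asks whether a list differs from the other tested miRNAs. fry asks whether a list differs from no change, so its p-values answer a different question. The lists covered the let-7, miR-15-16, miR-29 and miR-30 families, the miR-17-92, miR-23-27-24, miR-99-100-125, miR-183-96-182, Xp11 miR-532-502, Xq27 miR-506-514, 14q32 and C19MC clusters, the miR-200 family with miR-205, p53-responsive, thyroid carcinoma-associated and metabolic miRNAs, GC-rich probes sensitive to RNA quality, and markers of muscle, neural cells, blood, fibroblast and mesenchyme, endothelium, liver and embryonic stem cells.

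miRNAs were named by a rule set in advance. In each direction up to 12 past the threshold were to be named, filled up with those of largest fold change among miRNAs well above background on all 4 arrays with non-overlapping groups. miRNAs well above background on both arrays of 1 group and neither array of the other were to be named up to 5 per direction. No miRNA met any of these 3 conditions. The rule also took 14 fixed miRNAs whatever their value, and up to 4 tested members of each list, highest mean level first. miRNAs named outside this rule are marked where they appear. A miRNA not well above background on an array has only a bound there. The limma fit still took its scaled signal with the floor applied. The scramble means and fold changes of the 66 tested miRNAs therefore take in scramble replicate 2, where 0 of them were well above background. On that array the median signal of human miRNAs not well above background was 353, against its percentile of 409. Many undetected miRNAs thus entered near the percentile there and not at the floor. Between single arrays, the fold of such a miRNA is given as "at least", with the brighter side's scaled signal set against the higher of the other array's lowest well-above-background signal and the miRNA's own signal.

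The replicate numbers were checked for pairing through the correlation, across the 66 miRNAs, of the replicates' deviations from their group means. The check and the fits with a block are given with the alternatives. The alternatives covered the scaling, normexp background correction with an offset of 50, the software's total signal, the handling of probes, the floor, the filter on dim miRNAs, the prior, the replicate block, and leaving out each array. The fit was tested on simulated arrays with 66 miRNAs and 20 changed by 2 on the log2 scale. It recovered 100% of the changes at a replicate SD of 0.2 and 1% at an SD of 1.8. The pooled residual SD of the 4 arrays was 1.77. The number of arrays limits the precision of every comparison. Figures were drawn with matplotlib 3.10.9.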

Results

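The miRNA content of XTC.UC1 thyroid carcinoma cells was compared between cultures that received an siRNA against PRC, a coactivator of nuclear genes for mitochondrial respiration, and cultures that received a scramble siRNA. Each group had 2 arrays, from cultures labelled as biological replicates. The labels give 30 nM and 48 h for the PRC siRNA. Of 723 human miRNAs on the array, 128 were well above background on scramble replicate 1, 10 on scramble replicate 2, 69 on PRC siRNA replicate 1 and 162 on PRC siRNA replicate 2. The mean count was 69 ± 83.4 (SD, n = 2) for scramble and 115.5 ± 65.8 (SD, n = 2) for PRC siRNA, a difference smaller than the spread between replicates (exact permutation p = 0.667, two-sided, where 2 against 2 arrays cannot go below 0.333). The difference of 46.5 turned to −12.5 without scramble replicate 2.

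The 4 arrays did not measure the same pattern. Scramble replicate 2 shared no miRNA signal with the others: none of its 10 miRNAs was well above background on another array, and across the 66 miRNAs measured on all 3 other arrays its log2 signals correlated with those arrays at r between −0.15 and −0.13. The software located 53.8% of its spots, against 99.1% or more on the others, and the median local background was 962, against 52 to 54. Its hur control probes, which stood 10.3 to 92.7 times above the negative control probes on the other arrays, stood at 0.862 times. The 2 PRC siRNA arrays correlated with scramble replicate 1 at r = 0.72 and r = 0.70, and with each other at r = 0.41. These are correlations across miRNAs, which are not independent replicates.

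**Figure D1:**
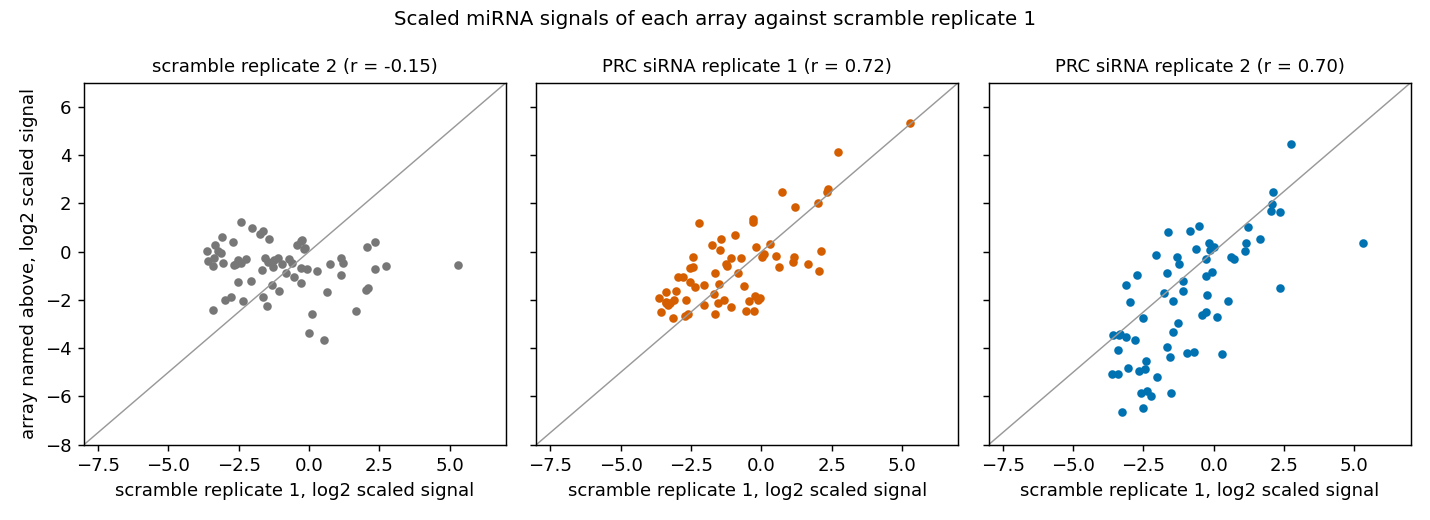
Log2 scaled signals (0 is an array's 75th percentile) of the 66 miRNAs well above background on the 3 arrays other than scramble replicate 2, with scramble replicate 1 on the horizontal axis and another array on each vertical axis. The points follow the line of equality loosely on the PRC siRNA arrays (r = 0.72 and 0.70) and not on scramble replicate 2 (r = −0.15).

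The comparison of PRC siRNA with scramble asks which miRNAs respond to loss of PRC. No miRNA passed. Each of the 66 tested miRNAs was well above background on 1 of the 2 scramble arrays, so the scramble means and the fold changes that follow are values of the fit, which takes in the signals of scramble replicate 2, and not measured folds. miR-210, a hypoxia-induced miRNA that targets mitochondrial proteins, stood at −3.88 ± 3.69 (log2, SD, n = 2) with PRC siRNA and −1.44 with scramble, a log2 fold change of −2.44 (SE 1.77). miR-17, of the MYC-responsive miR-17-92 cluster, stood at −2.33 ± 0.42 and −0.08 (log2 fold change −2.25). miR-21, an abundant miRNA of many carcinomas, stood at 2.85 ± 3.50 and 2.39 (log2 fold change 0.46), and miR-221 and miR-222, a pair often raised in thyroid carcinoma, had log2 fold changes of −2.67 and −1.12. The other tested miRNAs fixed in advance were miR-200c (0.23) and let-7a (0.95). Of the rest, miR-146b-5p was well above background on scramble replicate 1 and PRC siRNA replicate 2, miR-181c and miR-34a on PRC siRNA replicate 2 alone, and miR-378, miR-33a, miR-122 and miR-1 on no array.

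With limma, 0 of 66 tested miRNAs passed an adjusted p of 0.05 in either direction, the smallest adjusted p was 0.973, and 0 had an unadjusted p under 0.05. The SE was 1.77 on the log2 scale for every miRNA. Without scramble replicate 1, the array lacking miRNA signal was the only control, and 10 of the 76 miRNAs tested were well above background on it alone. That filter favoured lower values with PRC siRNA for those 10. Of the fits that left out 1 array, only this one had miRNAs past the threshold, all lower with PRC siRNA. With that control and filter they are no evidence of a response to PRC siRNA.

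The signs of the fold changes rest on an array without shared signal, so the values on the other 3 arrays are given as differences from scramble replicate 1 in log2 units, without a test. The PRC siRNA arrays were both lower for 17 of the 66 miRNAs, both higher for 10 and on opposite sides for 39, and the 2 sets of differences correlated at −0.14 (covariance −0.34). They share a control array: 3 unchanged arrays of equal spread, simulated 10000 times with the spread between the PRC siRNA replicates, gave a mean correlation of 0.50 (0.065 to 0.76), a covariance of 2.85 (0.24 to 6.31) and 44.0 miRNAs on the same side (32 to 58), against 27 here. A smaller spread on the control array would lower these simulated values. The median absolute difference was 2.08 between the PRC siRNA replicates, against 1.16 and 1.50 between either of them and scramble replicate 1. miR-21, on chromosome 17 at 55273418 to 55273437 (hg18, the stretch given for its probes), lay at 0.02 on PRC siRNA replicate 1 and −4.93 on replicate 2. miR-222 (X, 45491386 to 45491398) lay at 3.42 and −3.76, miR-221 (X, 45490552 to 45490570) at −0.01 and −3.26, and miR-210 (11, 558112 to 558127) at 1.26 and −3.96. miR-17 (13, 90800879 to 90800895) lay at −1.60 and −2.20, and miR-200c (12, 6943174 to 6943188) at 0.65 and 0.70. let-7a lay at −2.08 and 0.35; the file places its probes on chromosome 11 at 121522486 to 121522505, and other let-7a copies have their own loci.

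**Figure D2:**
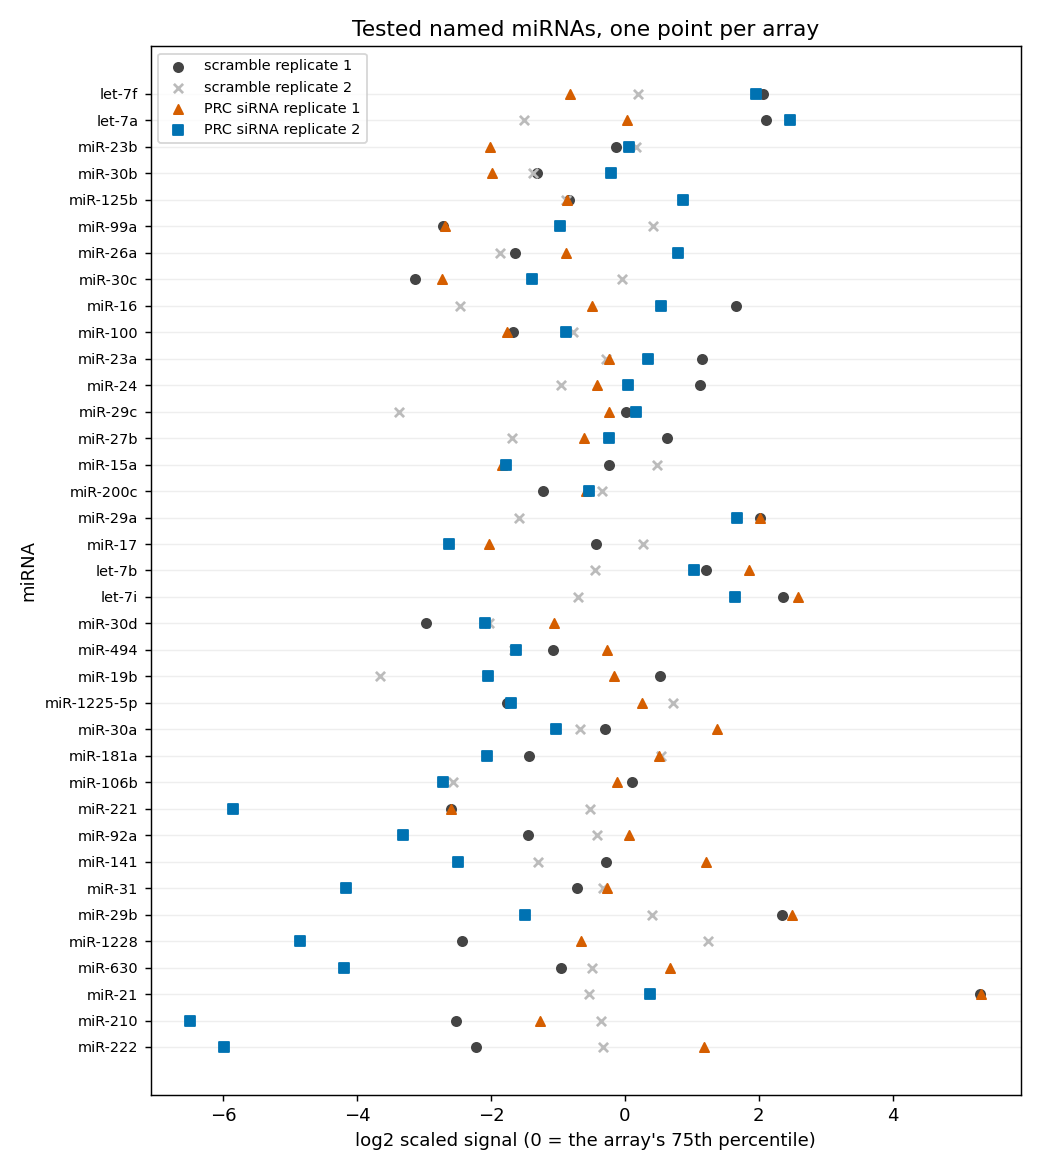
Log2 scaled signal on each of the 4 arrays for the 37 named miRNAs that were tested, ordered by the difference between the PRC siRNA replicates. The PRC siRNA replicates lie apart by more than their distance from scramble replicate 1 for many miRNAs, as for miR-222 (1.19 and −5.99), and the crosses of scramble replicate 2 are not well above background.

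Over all 66 miRNAs the median difference from scramble replicate 1 was 0.42 on PRC siRNA replicate 1 and −0.80 on replicate 2, against which the medians of the lists are to be read. The thyroid carcinoma-associated list had 7 tested members, of which 0 passed. All 7 were lower on PRC siRNA replicate 2 than on scramble replicate 1 (median −3.40) and 1 was lower on replicate 1 (median 0.92). Among them, miR-31 lay at 0.45 on replicate 1 and −3.45 on replicate 2, and miR-181a at 1.95 and −0.63. In the miR-17-92 cluster and its paralogs, growth-promoting miRNAs, 0 of 7 passed, 4 were lower on both arrays and all 7 on replicate 2. miR-19b lay at −0.69 and −2.57, miR-106b at −0.22 and −2.82, and miR-92a at 1.52 and −1.86. In the let-7 family, 0 of 7 passed and the median was −1.91 on replicate 1 and −0.04 on replicate 2. let-7f lay at −2.89 and −0.11, let-7b at 0.65 and −0.18, and let-7i at 0.23 and −0.72. The GC-rich list, whose probes respond to RNA quality, had 0 of 7 past the threshold and was higher on replicate 1 for all 7 (median 1.72) with a median of −0.68 on replicate 2. miR-1225-5p lay at 2.01 and 0.05, miR-1228 at 1.77 and −2.43, and miR-630 at 1.63 and −3.25.

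In the miR-30 family 0 of 6 passed, and 3 were higher on both PRC siRNA arrays (medians 1.11 and 0.51). miR-30c lay at 0.40 and 1.74, miR-30d at 1.92 and 0.88, and miR-30a at 1.66 and −0.74. miR-30b had scaled signals of −1.99 and −0.21 on the PRC siRNA arrays, against −1.32 on scramble replicate 1. In the miR-99-100-125 clusters 0 of 3 passed, with miR-125b at −0.04 and 1.69, miR-99a at 0.03 and 1.75, and miR-100 at −0.08 and 0.79. In the miR-23-27-24 clusters 0 of 4 passed and 3 were lower on both arrays. miR-23a lay at −1.39 and −0.80, miR-24 at −1.54 and −1.08, miR-27b at −1.25 and −0.87, and miR-23b at −1.89 and 0.19. In the miR-29 family, regulators of collagen genes, 0 of 3 passed, with miR-29a near its scramble level (0.00 and −0.35), miR-29b at 0.15 and −3.83, and miR-29c at −0.26 and 0.16. The metabolism and mitochondria list had 0 of 6 past the threshold (medians 0.28 and −0.68), with miR-26a at 0.77 and 2.44. The miR-15-16 family had 0 of 2 past the threshold, with miR-16 at −2.16 and −1.11 and miR-15a at −1.61 and −1.55. The miR-200 family had 0 of 2, with miR-141 at 1.49 and −2.21, and the 14q32 cluster 0 of 1, with miR-494 at 0.81 and −0.55. In each list 0 members also passed when adjusted over the list alone.

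By camera, 0 of 9 lists with at least 3 tested members passed (smallest adjusted p = 0.300, for the let-7 family, the miR-17-92 cluster and the miR-29 family; 0.849 with an estimated correlation and 0.978 by fry). camera compares a list with the other tested miRNAs, whose log2 fold changes were below 0 for 43 of 66, and it put the miR-23-27-24, miR-30 and miR-99-100-125 lists upward although their median log2 fold changes were −0.33, −0.12 and −0.09.

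Without scramble replicate 2, 128 miRNAs could be tested with 1 control array, which was taken to vary like the PRC siRNA arrays. limma called 0, and 3 had an unadjusted p under 0.05: miR-590-5p, miR-18a and miR-18b, named after their values were seen (adjusted p = 0.957 for each). All 3 were at the floor on both PRC siRNA arrays and so have only a bound there. Scramble replicate 1 lay at least 22.2-fold, 19.1-fold and 11.4-fold above PRC siRNA replicate 2. Above replicate 1 it lay at least 1.04-fold for miR-590-5p, and its miR-18a and miR-18b levels were under that array's detection limit. Of the 128, 62 were not well above background on at least 1 PRC siRNA array, and for 39 the level on scramble replicate 1 was under the detection limit of PRC siRNA replicate 1, which could not measure them at that level. Of the 7 members of the miR-17-92 cluster and paralogs measured on all 3 arrays, 4 were lower on both PRC siRNA arrays, as were 17 of all 66. With camera, 3 of 11 lists passed: the miR-17-92 list lower (adjusted p = 0.0128), and the miR-30 family (adjusted p = 0.0121, median 0.53) and the miR-99-100-125 clusters (adjusted p = 0.0486, median 0.53) higher than the other miRNAs. None of these lists passed with an estimated correlation or with fry, which tests a list against no change and not against the other miRNAs. With 3 arrays, both rest on so few residual degrees of freedom that hardly any list could pass. That outcome therefore does not count for or against these lists. Over the 66 miRNAs measured on all 3 arrays, 0 of 9 lists passed (smallest adjusted p = 0.0590, 0.866 with an estimated correlation and 0.957 by fry). In the fit over the 128 miRNAs, the GC-rich, let-7, metabolism and miR-29 lists were put upward by camera, without passing, although their medians were below 0. Without PRC siRNA replicate 1, and with the single PRC siRNA array taken to vary like the scramble arrays, 4 of 15 lists passed. All 162 miRNAs tested in that fit entered through PRC siRNA replicate 2. That filter favoured higher values for the blood markers and the fibroblast and mesenchyme markers, most of which were measured on this array alone. These 2 lists were higher than the other miRNAs, which with that filter is no evidence of a response to PRC siRNA. The miR-17-92 and thyroid carcinoma-associated lists were lower. No list passed with an estimated correlation or with fry, which tests against no change. Hardly any list could pass by either, since this fit also held only 3 arrays.

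Markers of other cell types differed between the arrays. Of the blood markers, 7 of 12 were well above background on PRC siRNA replicate 2, 1 on scramble replicate 1 and 0 on the other arrays. Of the fibroblast and mesenchyme markers, 7 of 11 were well above background on PRC siRNA replicate 2, and of the endothelial markers 1 of 2, with 0 on the other arrays. miR-451, an erythroid miRNA (17, 24212547 to 24212568), had a signal of 24282 on PRC siRNA replicate 2, 6.72 on scramble replicate 1 and 3.72 on PRC siRNA replicate 1, so that the scaled signal was at least 365-fold above the former and at least 69.6-fold above the latter. miR-126 of endothelium (9, 138684930 to 138684947) had a signal of 3370, at least 50.7-fold and 9.66-fold above those arrays, and miR-199b-3p of mesenchyme 1585, at least 23.8-fold and 4.54-fold above. The myeloid miR-223 (426) and the smooth muscle miR-145 (616) and miR-143 (230) were also well above background on this array alone. These were single arrays, with no test. They are the same array on which the thyroid carcinoma-associated list was lower. On PRC siRNA replicate 2 the muscle markers gave 1 of 8 and the neural markers 2 of 16, and the liver markers (2 on the array) and embryonic stem cell markers (15) gave 0 on every array.

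**Figure D3:**
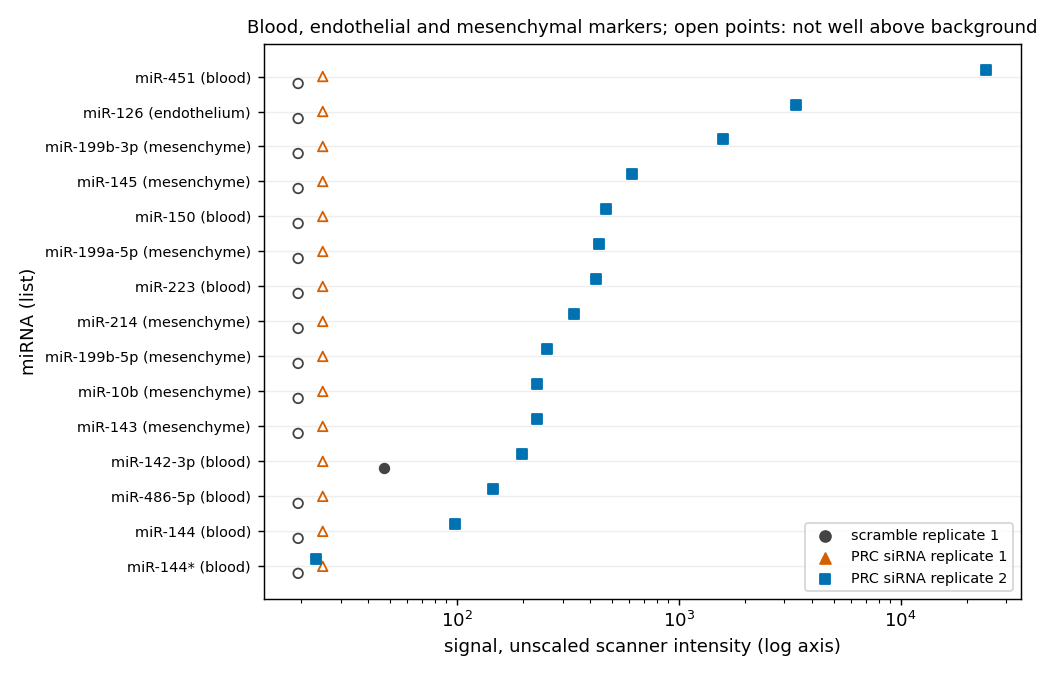
Signal (unscaled intensity, log axis) of the 15 blood, endothelial and mesenchymal markers well above background on PRC siRNA replicate 2, on the 3 arrays other than scramble replicate 2. Filled points are well above background; open points are not, and are drawn at the lowest well-above-background signal of their array (19.3 and 25.0). Of the 15, 1 was well above background on scramble replicate 1 and 0 on PRC siRNA replicate 1.

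The remaining lists were described by detection. The p53-responsive miRNAs were well above background for 4 of 11 on PRC siRNA replicate 2 and 0 on the others. The miR-183-96-182 cluster gave 2 of 6 on scramble replicate 1 and 1 on PRC siRNA replicate 2. The Xq27 cluster gave 0 of 13 on every array, and the C19MC cluster 1 of 47, on scramble replicate 2. Of 76 viral miRNAs, which have no known source in these cells, 4, 2, 3 and 4 were well above background on scramble replicates 1 and 2 and PRC siRNA replicates 1 and 2.

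In the authors' deposited table of processed values the column medians were −0.05 and −0.04 for the scramble replicates and −0.81 and −1.30 for the PRC siRNA replicates. The scramble columns held identical values for 446 of 596 probes, although the scanner files of the 2 arrays shared 0 spot signals. Across probes, no column of the table correlated with the scanner signal of its array beyond a Spearman coefficient of −0.03. The scale, centring and direction of the table therefore stay unknown here.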

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

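The tests in this part were chosen after the results were seen, and those on detection above an array's limit replaced a comparison of bounds whose outcome the choice of markers had fixed. No group had the 4 arrays needed to test for an outlying sample, and the design holds a single contrast.

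Outside the tested set, 50 human miRNAs were well above background on PRC siRNA replicate 2 and on neither scramble array, of which 1 carried shared miRNA signal, so that a single control array bears on them and gives a bound. Of the 25 blood, endothelial, and fibroblast and mesenchyme markers on the array, 14 were among them (56%), against 34 of 657 human miRNAs on no marker list (5.18%) and 2 of 41 muscle, neural, liver and stem cell markers. A stronger signal on that array is argued against by scramble replicate 1. Compared were miRNAs whose scaled level on PRC siRNA replicate 2 lay above the detection limit of scramble replicate 1. Markers were taken from the 7 lists fixed in advance. All 14 that qualified came from the blood, endothelial, and fibroblast and mesenchyme lists, whose detection prompted the test. The p-values therefore restate that detection in part, and they count miRNAs of shared clusters as independent. On scramble replicate 1, 1 of the 14 markers was well above background, against 93 of 111 miRNAs on no marker list (83.8%, one-sided Fisher's exact p = 1.6e-08). At least 4-fold above the limit it was 0 of 8 against 55 of 58 (the same exact test, p = 2.87e-08). On PRC siRNA replicate 1 it was 0 of 7 markers against 41 of 56 (73.2%; the same exact test, p = 0.000308; 0 of 3 against 26 of 28, p = 0.00222, at least 4-fold above), but the low signal of that array left only the brightest 7 of the 15 markers in the test, so an effect of the PRC siRNA stays open. RNA of other cell types, or another sample in place of the labelled one, also stays open: markers of the 7 lists were on this array alone for 16 of 66 (one-sided Fisher's exact p = 1.72e-06, with miRNAs of shared clusters counted as independent), but that detection prompted the explanation and cannot support it, and 1 of the 25 markers was also well above background on scramble replicate 1.

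In the authors' deposited table of processed values, 83.9% of the probes (500 of 596) had both PRC siRNA columns below both scramble columns. The table entered no comparison, its scale and direction are unknown, and its scramble columns are largely identical and its PRC siRNA columns follow each other (Spearman 0.93 across probes), so the values of a shift in one direction cannot be assigned to miRNAs.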

How the results depend on the processing

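The crossed block, and the fits that leave out scramble replicate 2 or PRC siRNA replicate 1 while changing a further choice, were chosen after seeing the data. The limits are the array without shared miRNA signal among the 2 controls, the low signal of PRC siRNA replicate 1 (75th percentile 202, lowest well-above-background signal 25.0), and the distance between the PRC siRNA replicates.

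The count of miRNAs past the threshold was 0 of 66 with limma and stayed at 0 under each other scaling, background correction, signal column, probe rule, floor, filter and prior run, with a replicate block, with the size threshold, and in the added fits. Over the fits that left out 1 array it ranged from 0 to 8, the 8 without scramble replicate 1. The deviations of same-numbered arrays correlated at −0.22, which cannot show pairing or its absence, since 1 of the 4 arrays carried no shared miRNA signal. The replicate block gave 0 calls, and the crossed block also 0 (unadjusted p under 0.05: 0 and 2). The difference in the count of miRNAs well above background, 46.5 in the comparison of all arrays, ranged from −12.5 (without scramble replicate 2) to 105.5 when 1 array was left out.

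The count of lists past the threshold, 0 of 9, became 1 with normexp (let-7, upward) and 5 of 22 with no filter (let-7, miR-29, miR-30, blood, and fibroblast and mesenchyme, upward), and it ranged from 0 to 4 when 1 array was left out, with the 4 without PRC siRNA replicate 1, where it was 0 with an estimated correlation or fry. Upward is relative to the other miRNAs. With no filter, 686 of the 723 miRNAs were lower with PRC siRNA (median log2 fold change −3.06), but 535 were well above background on no array. miRNAs not well above background had a median signal of 353 on scramble replicate 2, near its percentile of 409. On the other arrays that median was −7.75 to −6.36, so most of them entered at the floor there. The lower values therefore do not show a response to PRC siRNA. With a replicate block the count of lists past the threshold was 0. With scramble replicate 2 left out it was 4 with quantile normalization, 1 with normexp, 5 with gTotalGeneSignal and 2 with the percentile over all human miRNAs; the miR-17-92 list (lower) and the miR-30 family (higher) were among the lists passing in each of these but normexp. An estimated correlation and fry were run with the scaling of the report alone and passed no list. With 1 array left out, hardly any list could pass by either, so that outcome does not count against the lists. No list passed over the 66 miRNAs measured on all 3 other arrays. The cause was not tested.

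The scaling moved the median log2 fold change of the 66 miRNAs from −0.62 by 3.11 with the percentile over all human miRNAs, 2.43 with quantile normalization, 0.51 with the median, 0.38 without scaling and −0.19 with normexp. At most 162 of the 723 human miRNAs were well above background on an array, fewer than lie above the 75th percentile over all 723. That percentile therefore takes in undetected signals, whose median was 353 on scramble replicate 2 and −7.75 to −6.36 on the other arrays. Results with it are to be read with that limit. The percentile over all human miRNAs, the median and no scaling move every miRNA named here by the same amount, so the 33 sign changes under these 3 settings follow from that shift alone and take in the values between minus the shift and 0. Of 629 combinations of the 37 named miRNAs and a setting, 113 had the opposite sign and 0 passed the threshold (adjusted p between 0.180 and 1). With the 75th percentile over all human miRNAs, 20 named miRNAs changed sign: let-7f 2.55, miR-100 3.02, miR-106b 2.93, miR-1225-5p 2.90, miR-1228 0.95, miR-15a 1.18, miR-17 0.86, miR-181a 2.78, miR-210 0.68, miR-221 0.44, miR-222 1.99, miR-23a 2.73, miR-23b 2.12, miR-24 2.84, miR-29b 2.24, miR-30c 2.64, miR-31 1.42, miR-630 2.08, miR-92a 2.43 and miR-99a 2.44. With the median in place of the percentile, 7 named miRNAs changed sign: miR-100 0.42, miR-106b 0.33, miR-1225-5p 0.30, miR-181a 0.18, miR-23a 0.13, miR-24 0.24 and miR-30c 0.033. With quantile normalization, 20 named miRNAs changed sign: let-7f 1.49, miR-100 2.21, miR-106b 2.68, miR-1225-5p 1.68, miR-1228 3e-04, miR-15a 0.44, miR-17 0.35, miR-181a 1.62, miR-210 1.05, miR-221 0.74, miR-222 1.86, miR-23a 1.79, miR-23b 1.14, miR-24 2.07, miR-29b 1.05, miR-30c 1.39, miR-31 1.13, miR-630 1.72, miR-92a 1.85 and miR-99a 1.23. Without scaling, 6 named miRNAs changed sign: miR-100 0.29, miR-106b 0.20, miR-1225-5p 0.17, miR-181a 0.052, miR-23a 1e-04 and miR-24 0.11. With normexp, 12 named miRNAs changed sign: let-7f 1.01, miR-141 −0.88, miR-19b −0.77, miR-200c −0.10, miR-21 −0.048, miR-23a 0.090, miR-23b 0.037, miR-24 0.083, miR-30a −0.19, miR-30b −0.27, miR-30d −0.74 and miR-494 −0.55. With the brightest probe alone, 2 named miRNAs changed sign: let-7f 0.32 and miR-100 0.13. With the mean log2 over probes, 2 named miRNAs changed sign: miR-200c −0.092 and miR-23a 0.66. With 1 array left out, 30 of the 37 changed sign: let-7a −0.87 to 2.76, let-7f −1.95 to 0.83, let-7i −0.25 to 2.82, miR-100 −0.54 to 0.35, miR-106b −1.52 to 1.15, miR-1225-5p −1.45 to 1.03, miR-125b −0.011 to 1.72, miR-141 −1.70 to 2.00, miR-16 −1.63 to 2.49, miR-181a −1.62 to 0.96, miR-19b −1.63 to 2.55, miR-200c −0.21 to 0.68, miR-21 −2.45 to 3.38, miR-210 −5.05 to 0.17, miR-222 −4.71 to 2.46, miR-23a −1.10 to 0.33, miR-23b −2.04 to 0.038, miR-24 −1.31 to 0.77, miR-27b −1.06 to 1.26, miR-29a −0.18 to 3.43, miR-29b −2.86 to 1.12, miR-29c −0.051 to 3.35, miR-30a −0.55 to 1.85, miR-30b −0.65 to 1.13, miR-30c −2.02 to 1.07, miR-31 −3.65 to 0.25, miR-494 −0.26 to 1.09, miR-630 −3.48 to 1.40, miR-92a −2.38 to 1.00 and miR-99a −2.24 to 0.89. The causes of the other 80 sign changes were not tested.

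Not run were the filter to miRNAs well above background on all 4 arrays, which left 0, the slide or scan block, since all arrays share 1 scan, and the authors' value table, whose scale could not be found. The planned scalings over miRNAs well above background on all 4 arrays used the 66 in their place.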

Other observations

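Of the tests in this part, the within-miRNA tests of probe length were fixed before their results were seen and the others after.

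Scramble replicate 2 carried no signal shared with the other arrays. A spot grid flipped or shifted by whole rows or columns is argued against within the range searched. Over 4 orientations and shifts of up to 40 rows and 20 columns the highest correlation of its spots with scramble replicate 1 was 0.0397. PRC siRNA replicate 2 reached 0.864. A grid that lay between spots, was rotated or was further off would not be found by this search. Such a grid stays open for scramble replicate 2. A difference in the cells' miRNA is argued against as the whole cause by the array's bright corner probes, which stood at 0.986 times the dark corner probes, against 2.38 to 4.30 times on the other arrays. Spots read without labelled RNA remain a candidate explanation, since the hur control probes stood at 0.862 times the negative controls.

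Each list's median difference from scramble replicate 1 was ranked among 10000 random lists of its size and level. The let-7 family lay at the 0.260 percentile on PRC siRNA replicate 1 (median −1.91) and the 80.1 percentile on replicate 2 (−0.04), and the GC-rich list at the 98.2 percentile (1.72) and the 63.6 percentile (−0.68). The thyroid carcinoma-associated list lay at the 55.3 percentile on replicate 1 (0.92) and the 0.440 percentile on replicate 2 (−3.40), and the miR-30 family at the 77.9 percentile (1.11) and the 99.4 percentile (0.51). The percentiles describe these arrays and give no test of the siRNA or of the difference between the replicates. The miR-17-92 list lay at the 8.56 percentile on replicate 1 and the 4.78 percentile on replicate 2.

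On PRC siRNA replicate 1 the difference from scramble replicate 1 fell with the length of the genomic stretch given for a miRNA's probes (10.5 to 21.5 bases; across 66 miRNAs, Spearman −0.62, Pearson −0.60, permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 2e-05 over 2 relations). On replicate 2 it did not (Spearman 0.14, Pearson 0.11, permutation p = 0.271, adjusted p = 0.271). These permutations count miRNAs of a family as independent and compare single arrays, so they say nothing on whether the trend would recur in another culture. Before the test, hybridization or washing that differed between the arrays was predicted to lower the longer probe of a miRNA. No measure of such a difference was available, so this direction was assumed. The longer probe was the lower for 23 of 37 miRNAs (62.2%, exact sign test p = 0.188), which leaves such a difference open. On PRC siRNA replicate 2 the longer probe was the lower for 28 of 74 miRNAs (exact sign test p = 0.0474, adjusted p = 0.0948 over the 2 arrays; median difference 0.11), the opposite direction. On PRC siRNA replicate 1 the median difference within a miRNA was −0.0474. The slope within miRNAs was −0.07 ± 0.05 (SE) log2 units per base, against −0.32 across miRNAs. The probes of a miRNA differed by a median of 1 base, for which the slope across miRNAs gives −0.32. That is smaller than the difference set in advance to count against a difference in the cells' miRNA alone. The test could therefore hardly go against that explanation, which stays open. A property that all probes of a miRNA share, such as base composition, was not tested and may contribute. On this array the GC-rich list lay at the 98.2 percentile (median 1.72) and the let-7 family at the 0.260 percentile (−1.91). Their relation to target length was not tested.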
